A study of Rattus norvegicus with 18 samples.

How the data were processed

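Each of 9 cell populations from rat testis had been put on 2 types of 1-colour oligonucleotide array, named A and B here, which makes 18 arrays with 1 array per population and type. Per the labels, 50 ng of total RNA went through 2 rounds of amplification. The deposited values are intensities on a linear scale, 1 signal per probe set, which the authors had scaled array by array to an average of 250. Per the labels, the detection calls of the authors used a Tau of 0.015, and those calls are not among the values used here. The software, its version and the treatment of background are not given in the sources used here. The mean of the central 96 percent of the values was checked on each array and lay between 249.91 and 249.95. The share of probe sets at or above the floor of 50 was 59.4% to 70.3% on type A and 68.0% to 74.3% on type B. The scale factors mean that the floor corresponds to unscaled signals from 33.1 to 127.9 on type A and from 12.5 to 47.8 on type B. The signal ratio of the 3' to the middle probe sets was 1.41 to 8.09 for Gapdh and 4.45 to 11.5 for actin.

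Type A held 15923 probe sets and type B 15333. On each type 57 control probe sets were left out, and 100 others on both types were counted on type A alone, which left 31042 counted probe sets, 15866 on type A and 15176 on type B. On type A 12789 probe sets had 1 gene, 312 had several and 2822 had none in the annotation, and on type B these were 7570, 100 and 7663. Only probe sets with 1 gene were named, with positions from the GRCr8 assembly. In the gene lists each gene was read from its brightest probe set by mean log2 signal, on type A where that type has the gene and otherwise on type B, for 13810 genes. Of the list genes 119 had several probe sets, and none was called in both directions in any comparison. Between 5 and 11 list genes per comparison were called only by another of their probe sets. These include Itga6, 7.38-fold higher in laminin-binding than in non-binding cells on type B, Crem, 10.4-fold higher on STO day 20 than day 1 on type B, and Fgfr3, 6.34-fold lower there on type B.

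Signals were raised to the floor of 50 and taken to log2. A probe set was called where the brighter side was at least 250 and the fold at least 3, and the comparison with both somatic fractions asked for this against each of them. A fold against a signal under the floor is given as at least that many fold. The comparisons were laminin-binding against non-binding cells, laminin-binding cells against both somatic fractions, STO day 20 against day 1, MSC1 against STO on day 20, and the tubular somatic against the interstitial fraction. The named genes of each comparison are the 10 with the largest folds in each direction among calls above the floor on both sides, in the STO series among probe sets that moved one way at every step, and any called member of the gene lists. The text gives the first 4 to 6 of the 10. In every comparison the dim side of a named gene can lie just over the floor, where its fold is less sure. A culture trend was fitted with limma's linear model and moderated test on log2 culture day, with the variance trend on, on 4 STO arrays per type and 2 residual degrees of freedom, for probe sets with a mean signal of at least 100, and adjusted by the Benjamini-Hochberg method over both types at 0.05. The spread in this test is the departure from a straight line and not that of repeated cultures. Correlations across probe sets used the same minimum of 100.

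The 23 gene lists were undifferentiated spermatogonia, differentiating spermatogonia, general germ cell, meiotic prophase, pachytene and later, haploid spermatid, Sertoli, Leydig and steroidogenic, peritubular myoid and smooth muscle, fibroblast and extracellular matrix, macrophage and leukocyte, endothelial, red blood cell, cell cycle, immediate early, p53 and growth arrest, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, unfolded protein response, oxidative stress response, interferon response, and GDNF and FGF signalling. They hold 400 genes on the arrays, of which 10 are in more than 1 list, among them 8 shared by the undifferentiated spermatogonia and the GDNF and FGF signalling lists and Sycp3, shared by the general germ cell and meiotic prophase lists. Results for lists that share genes are not independent in any comparison. A gene counted as measured where at least 1 side was above the floor. The median log2 fold of a list was placed among 10000 random lists of the same size matched on signal in 20 bins, and a list with fewer than 3 measured genes got no median. A median in the outer 2.5% on either side was called in a tail, and chance gives 0.55 to 0.575 lists per tail and comparison if genes move independently. The random lists draw genes independently, whereas genes of a list can move together in a single library. More lists than this can therefore reach a tail without an effect of the condition. The comparisons had 4, 7, 2, 2 and 6 lists in the lower and 5, 5, 2, 5 and 3 in the upper tail, in the order given above.

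These comparisons, thresholds, gene lists and alternatives were chosen before the data were examined, apart from those said to be chosen after the data were seen. The alternatives were a floor of 25 or 100, no minimum on the brighter side, quantile normalization within each type, scaling to a common 75th percentile, a 2-fold threshold, a slope on culture day in place of its log2, leaving out each day of the trend, the mean over a gene's probe sets or type A alone for the lists, and a minimum mean signal of 250 for the array spread. Added later were STO day 10 in place of day 20, each somatic fraction alone, and the laminin comparison without probe sets higher in a somatic fraction. The calls were tested on simulated data, in which 183 of 198 probe sets with a 4-fold change were recovered (92.4%) with 0 false calls. The noise simulated for these calls had a standard deviation of 0.17 on the log2 scale, far under the 3-fold threshold. The 0 false calls therefore followed from this setting. They do not give the rate of false calls in the real data, where single probe sets differed more between the array types. In simulated trends all 100 changes of 4-fold and all 100 of 8-fold were recovered, with 7 false calls among 15866 unchanged probe sets. The simulated changes were straight lines on log2 culture day, as in the fitted model, in brighter probe sets and with array noise alone. Their recovery does not show the power for changes of another shape or against the spread between cultures. The tools were Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.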

Results

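Transcript levels were measured in 9 cell populations from the testes of 22-day-old rats with 18 oligonucleotide arrays, 1 of each of 2 array types (A and B) per population. 7 populations were germ cells: cells that bound to laminin, a basement membrane protein, cells that did not bind, cells kept on STO feeder layers for 1, 5, 10 or 20 days, and cells kept on MSC1 feeder layers for 20 days. STO is a mouse embryonic fibroblast line and MSC1 is a mouse line of Sertoli cells, the somatic cells that surround germ cells inside the tubule. The other 2 populations were somatic, namely interstitial cells from the tissue between the tubules and somatic cells of the tubules. The labels mark the laminin-binding and non-binding cells as cultured without giving a day, and they do not say whether the binding cells were those placed on feeders. Each array had been scaled to a mean signal of 250, with scale factors from 0.391 to 1.51 on type A and from 1.05 to 4.01 on type B. There were no replicates, so folds between single libraries are given without an error or p-value, and the number of arrays limits their precision.

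The germ cell libraries carried germ cell transcripts such as Sycp3 and Tex15, and the somatic libraries carried collagens, steroidogenic enzymes and Sertoli cell transcripts. Some libraries of cells on feeders carried collagens too, as Col1a1 read 540 on STO day 20, 693 on MSC1 and 315 in the tubular fraction. The median level of the 8 genes of the general germ cell list lay 2.17 above each gene's mean in non-binding cells, on the log2 scale, and -2.74 and -2.99 from it in the interstitial and tubular fractions. The median level of the 9 haploid spermatid genes with a signal was between -0.18 and 0.07 in the 9 populations, although single genes differed more, such as Odf2 of the sperm tail with a signal of 4231 in non-binding and 263 in binding cells. The median of the 13 endothelial genes was between -0.15 and -0.01, and that of the 3 red blood cell genes with a signal between -0.23 and 0.40. The ratio of the 3' to the 5' signal of Gapdh, which grows as RNA is degraded or shortened in amplification, was in most cases higher on feeder layers, while that of actin overlapped more. For Gapdh on type A it was 14.7 to 29.7 in the 5 libraries of cells on feeders and 5.63 to 11.2 in the 4 others, and on type B it was 15.0 to 27.1 and 5.33 to 16.7. For actin it was 25.8 to 94.3 and 8.91 to 67.3 on type A and 21.0 to 95.4 and 11.6 to 48.9 on type B, with MSC1 lowest on feeders and under both somatic fractions. The library of each population matched its own partner on the other array type best, by the levels of 100 probe sets that both types hold, in 9 of 9 cases. The correlation with the partner was 0.83 to 0.95 across these probe sets, and the highest with any other population was 0.64.

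**Figure D1:**
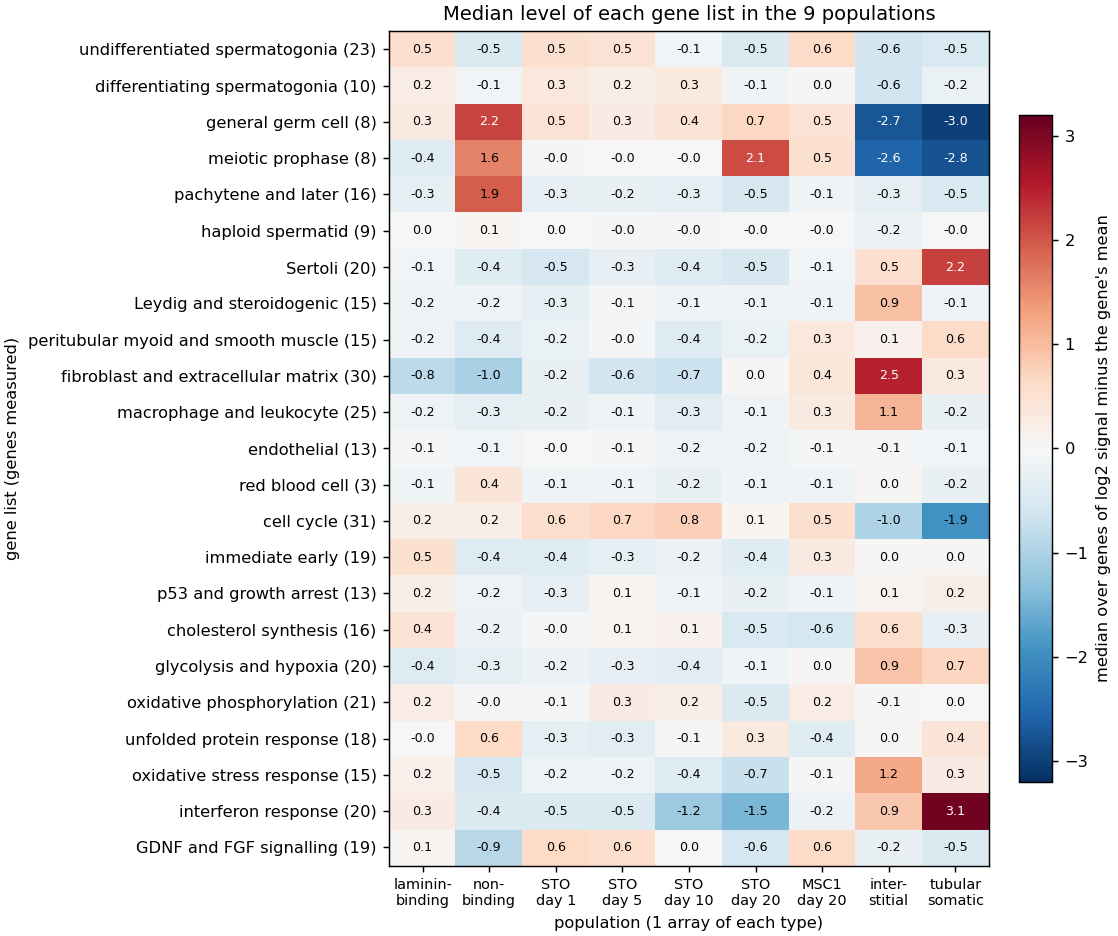
Median level of each of the 23 gene lists (vertical, with the number of genes that have a signal) in the 9 populations (horizontal, 1 array of each type), as log2 signal minus the gene's mean over the populations. Meiotic prophase genes stand at 1.58 in non-binding cells and 2.09 on STO day 20, and pachytene genes stand at 1.94 in non-binding cells and -0.51 on STO day 20.

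The same 100 probe sets gave the size of the array error. The log2 folds of types A and B differed with a standard deviation per array type of 0.21 for laminin-binding over non-binding cells, 0.20 for STO day 20 over day 1, 0.27 for MSC1 over STO on day 20 and 0.25 for the tubular over the interstitial fraction. Over all pairs of populations the mean was 0.25, so that 2 standard deviations corresponded to a 1.40-fold difference, less than the 3-fold threshold used for a call. Single probe sets differed more, by up to 2.09 in log2 fold over all pairs, and 6, 1, 5 and 1 of the 100 passed 3-fold on only 1 of the types in these 4 comparisons. This spread covers the arrays and not the animals, cultures or amplification.

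**Figure D2:**
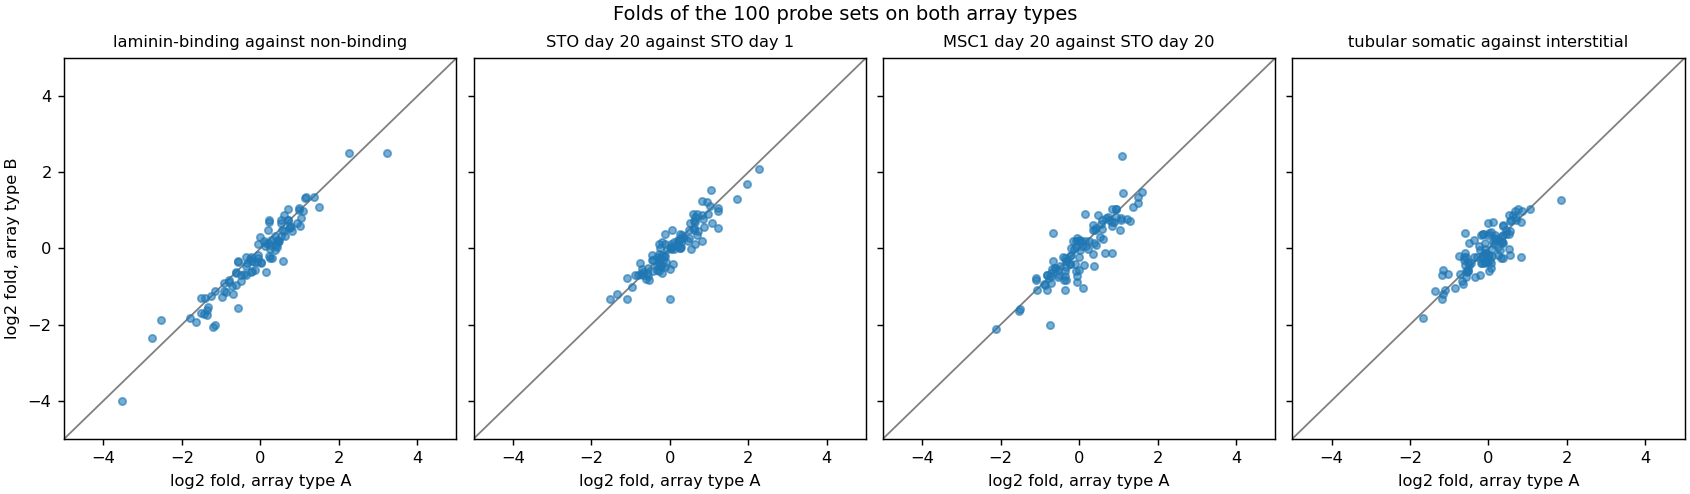
Log2 fold on array type B (vertical) against array type A (horizontal) for the 100 probe sets on both types, 1 point per probe set and 1 panel per comparison, with the line of equal folds. The points follow the line, with a correlation across probe sets from 0.82 to 0.96.

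Laminin-binding cells carried more of the transcripts of early spermatogonia, and non-binding cells more of those of spermatocytes. Of 20 measured genes of undifferentiated spermatogonia, the list that holds stem cell markers, 7 were higher in binding cells and none was lower. Ret, the signalling subunit of the receptor for the growth factor GDNF, was 8.10-fold higher (signal 707 against 87.3), the RNA-binding protein gene Nanos3 was 6.52-fold higher and the transcription factor gene Sox3 6.90-fold higher. Gfra1, which encodes the GDNF-binding subunit of the receptor, was 2.03-fold higher, under the threshold. On the other side, 8 of 16 pachytene genes were lower in binding cells, led by Ldhc, a lactate dehydrogenase of spermatocytes and sperm, at 53.7-fold lower, and Crisp2, a protein of the sperm acrosome, at least 76.2-fold lower. Meiotic prophase genes were lower for 4 of 8, with Spo11, which makes the DNA breaks of meiotic recombination, at least 48.3-fold lower and the synaptonemal complex gene Sycp2 15.6-fold lower.

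In the GDNF and FGF signalling list 6 of 16 genes were higher in binding cells, among them the ETS factor gene Etv4 at 5.03-fold and Spry2, a feedback inhibitor, at least 5.50-fold. Of 8 genes of differentiating spermatogonia, 3 were higher, namely the DNA methyltransferase genes Dnmt3a (6.74-fold) and Dnmt1 (3.90-fold) and the cyclin gene Ccnd2 (3.76-fold), and Dmrtb1 was 6.38-fold lower. Among 17 immediate early genes, which respond within minutes to growth factors or stress, 7 were higher, with Fosb at 8.84-fold, Egr4 at 6.11-fold and Egr1 at 5.77-fold. Of 18 interferon response genes 4 were higher, including the immunoproteasome genes Psmb9 (8.002-fold) and Psmb8 (3.73-fold). The signal of Psmb8 was 914 in binding cells, 245 in non-binding cells and 3397 in the tubular somatic fraction. A Sertoli cell gene, Cldn11, was 4.07-fold higher, with a signal of 637 in binding cells and 3389.9 in the tubular fraction. The remaining 15 of 16 Sertoli genes passed no call. Of 18 genes of the unfolded protein response 4 were lower, with the chaperone gene Canx at 8.58-fold and Herpud1 at 4.97-fold. Cell cycle genes went both ways, as Mcm2, Mcm4 and Mcm7 of the replicative helicase were 3.87-fold, 3.76-fold and 3.82-fold higher and Top2a and Bub1 were 3.19-fold and 4.56-fold lower, with 26 of 31 not called. General germ cell genes were lower for 4 of 8, such as Tex101 at 4.57-fold and Tdrd1 at 4.37-fold. The glucose transporter gene Slc2a3 was 19.7-fold lower, one of 4 lower genes among 16 of glycolysis and hypoxia. In the p53 and growth arrest list 1 of 11 genes was lower, the cyclin gene Ccng1 at 6.18-fold.

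The largest folds measured on both sides were those of Inf2, a formin that shapes actin, at 24.2-fold higher, Rhbdf2 at 17.6-fold, Vav2 at 17.4-fold, Patz1 at 15.4-fold, Rbm43 at 14.2-fold and Nptx1 at 13.9-fold. Lower in binding cells were C2cd6, a gene of the sperm flagellum, at 62.9-fold, Cmtm2a at 56.3-fold, Ldhc and Cage1 at 44.5-fold. Inf2 (gene 362790) lies on chromosome 6 of the GRCr8 assembly from 137470259 to 137497039, and C2cd6 (gene 501147) on chromosome 9 from 67929069 to 68024993. In all, 1132 of 31042 probe sets were higher and 1186 lower at 3-fold or more, a share higher of 48.8%, and with arrays scaled to the same 75th percentile these were 917 and 1419, a share of 39.3%. The median log2 fold was 1.27 for undifferentiated spermatogonia, 1.15 for GDNF and FGF signalling, 1.08 for differentiating spermatogonia, 1.23 for immediate early genes and 1.09 for interferon response genes, each above at least 98.8% of random lists matched on signal. With the mean over a gene's probe sets the immediate early median was 0.75, and with a floor of 25 that of differentiating spermatogonia was 0.69. On the lower side the median was -2.07 for pachytene genes, below all 10000 random lists and between -2.83 and -1.46 under the alternatives, -1.60 for general germ cell genes, -1.58 for meiotic prophase genes and -0.68 for the unfolded protein response, each below all but 1.10% of them or fewer. The median of all genes was 0.21, and 0.06 after quantile normalization. Relative to 0.21 the medians were 1.06 for undifferentiated spermatogonia, 0.94 for GDNF and FGF signalling, 1.02 for immediate early genes, 0.88 for interferon response genes and -2.27 for pachytene genes. Without probe sets that were at least 3-fold higher in a somatic fraction than in non-binding cells, the number higher in binding cells was 642, a setting chosen after the data were seen.

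Against both somatic fractions, laminin-binding cells were higher in germ cell and replication transcripts and lower in matrix, Sertoli cell and glycolytic transcripts. In the general germ cell list 7 of 8 genes were higher than in either fraction, with the synaptonemal complex gene Sycp3 at 14.8-fold, Tex14, needed for the bridges between germ cells, at 12.6-fold and the piRNA helicase gene Mov10l1 at least 13.7-fold. Undifferentiated spermatogonial genes were higher for 6 of 19, among them the adhesion gene Epcam at least 43.1-fold, Sox3 at least 31.4-fold and Ret at least 14.1-fold. Of 31 cell cycle genes 11 were higher, with the helicase genes Mcm5 at 14.9-fold and Mcm7 at 10.8-fold and the proliferation marker Mki67 at 4.76-fold. Of 29 fibroblast and extracellular matrix genes 12 were lower, including the collagen chaperone gene Serpinh1 at least 15.6-fold, Col5a2 at 14.2-fold and the intermediate filament gene Vim at 7.07-fold. The fold of a gene is that against the nearer fraction, so that a call held against each of them, and the list medians are set against the mean of both.

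Sertoli genes were lower for 4 of 17, with Vnn1 at least 19.9-fold and Aldh1a1, which makes retinoic acid, at 17.7-fold, and steroidogenic genes for 1 of 14, the cholesterol carrier gene Star at 6.36-fold. Some Sertoli genes had a signal above the floor in binding cells, as Dhh read 466 against 2526 in the tubular fraction and Wt1 155 against 1273. The median signal of the laminin-binding arrays was 92.9 on type A and 128 on type B. The median level of the Sertoli list was -0.10 in binding cells, -0.39 in non-binding cells and 2.18 in the tubular fraction. Without detection calls, these values do not show that tubular somatic cells were present among the binding cells. Of 19 glycolysis and hypoxia genes 5 were lower, such as Tpi1 at 8.12-fold, P4ha1 at 8.74-fold and Ldha at 5.29-fold, and of 13 myoid and smooth muscle genes 3 were lower, led by Cald1 at 12.6-fold. Interferon response genes were lower for 4 of 20, led by Ifit2 at 17.1-fold, and of 15 oxidative stress genes 4 were lower and 1 higher, with Gsta1 at 14.4-fold lower. In contrast with the matrix genes, the immediate early genes Fosb and Egr4 were at least 22.0-fold and at least 17.8-fold higher, Fos was 6.61-fold and Ier2 3.65-fold higher, and Ier3 was 3.38-fold lower, with 13 of 18 not called.

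Among genes above the floor on both sides, the first by fold were Ccdc88c at 80.6-fold, Tnrc6c, a partner of Argonaute in silencing by microRNAs, at 61.1-fold, the germ line gene Tex19.2 at 34.2-fold, Tmem130 at 31.6-fold and Tex15, needed for meiotic recombination, at 31.0-fold. On the lower side were the collagen cross-linking enzyme gene Lox at 17.9-fold, Carmil1 at 17.8-fold, Aldh1a1 at 17.7-fold and Dera at 17.5-fold. Ccdc88c (gene 362770) lies on chromosome 6 from 125899337 to 126019162 and Lox (gene 24914) on chromosome 18 from 48162889 to 48175640 (GRCr8). The counts were 1028 probe sets higher and 842 lower than in both fractions. The median log2 fold was 3.25 for general germ cell, 3.22 for meiotic prophase and 1.82 for cell cycle genes, above all random lists, and 1.41 for undifferentiated and 1.33 for differentiating spermatogonia, above at least 98.9% of them. It was -2.71 for matrix, -1.80 for Sertoli and -1.21 for interferon response genes, below all random lists, and -1.13 for glycolysis and hypoxia, -0.67 for macrophage and leukocyte, -0.66 for myoid and -0.63 for steroidogenic genes, below all but 1.58% of them or fewer. The medians with the widest ranges under the alternatives were those of differentiating spermatogonia, down to 0.36 with a floor of 25 or type A alone, of Sertoli genes, -1.02 with the mean over a gene's probe sets, of myoid genes, -1.91 with a floor of 100, and, relative to its size, of steroidogenic genes, -0.26 with a floor of 25. Against 1 fraction alone, a setting chosen after the data were seen, 1791 were higher and 2122 lower than in the interstitial fraction, and 1488 higher and 1631 lower than in the tubular fraction.

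On day 20 on STO feeders, transcripts of undifferentiated spermatogonia were lower and those of meiotic prophase higher than on day 1. The larger part of the change came after day 10 for most called probe sets. The median level of the meiotic prophase list was -0.03, -0.02, -0.0001 and 2.09 on days 1, 5, 10 and 20, so its rise rests on the day 20 library alone. That of undifferentiated spermatogonia was 0.51, 0.47, -0.09 and -0.47. Ret had signals of 1729.5, 768, 318 and 48.6 on days 1, 5, 10 and 20, an at least 34.6-fold fall, and Gfra1 was 5.60-fold lower on day 20 than on day 1. Of 21 measured genes of undifferentiated spermatogonia 7 fell and none rose, among them Nanos3 at least 6.53-fold and Snap91 at least 9.83-fold. Of 8 meiotic prophase genes 6 rose, namely Spo11 at 23.5-fold (signal 102 to 2381), Sycp2 at 11.6-fold, Sycp1 at 4.25-fold, Smc1b of the meiotic cohesin complex at 3.71-fold, Sycp3 at 3.37-fold and Stag3 at 3.32-fold. None of 12 pachytene genes passed a call by the probe set used for its list, and Ldhc had a signal of 149 on day 1 and 24.7 on day 20. Crem, also of the pachytene list, rose 10.4-fold by another probe set, on type B (signal 145 to 1506).

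GDNF and FGF signalling genes fell for 5 of 17, including Etv4 at 3.58-fold and Dusp6, a phosphatase of the ERK pathway, at 3.11-fold. Unfolded protein response genes rose for 3 of 18, namely Canx at 6.68-fold, Herpud1 at least 5.60-fold and Sdf2l1 at 4.08-fold. Of 16 interferon response genes 4 fell, among them Psmb8 at 9.88-fold and the transcription factor gene Irf1 at 7.97-fold. Markers of other cell types moved with day 20 as well. In the fibroblast and extracellular matrix list 5 of 26 genes rose, with Lox at least 14.6-fold, Col1a2 at 7.39-fold and Col1a1 at 4.06-fold, and Fbn1 fell 3.196-fold. Of 18 macrophage and leukocyte genes 3 rose, namely the lysozyme gene Lyz2 at 6.72-fold, Ccl2 at 4.51-fold and Spp1 at 3.42-fold, and of 9 steroidogenic genes 2 rose, Star at 6.47-fold and Hsd11b1 at least 5.16-fold. No Sertoli or myoid gene passed a call.

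Among probe sets above the floor on all days that moved one way at every step, the first rising genes were Ifi30, a lysosomal thiol reductase, at 14.0-fold, Sycp2, the transcription factor gene Crem at 10.4-fold by its probe set on type B, and Pcdh17 at 10.0-fold. The first falling genes were Ssh1, a phosphatase of the actin regulator cofilin, at 37.8-fold, Nptx1 at 26.6-fold, Cdca7l at 15.6-fold, Epb41l3 at 15.6-fold, Fbxo41 at 15.2-fold and Reln, a secreted matrix protein, at 13.4-fold. Ifi30 (gene 290644) lies on chromosome 16 from 18709570 to 18713635 and Ssh1 (gene 304580) on chromosome 12 from 48281756 to 48343812 (GRCr8). Between days 1 and 20, 621 probe sets were higher and 819 lower. From day 1 to day 10, a setting chosen after the data were seen, 44 were higher and 142 lower, of which 18 and 121 were also called on day 20, and from day 10 to day 20 the counts were 379 and 395. More of the log2 change came after day 10 than before it for 493 of the higher and 579 of the lower probe sets, with a median share of 72.8% and 65.0%. Of 17364 probe sets with a signal on all days, 6.04% rose and 7.57% fell at every step, against 4.17% each way with no order. The 4.17% takes the 4 libraries as exchangeable. Day 20 differed from the other days by 774 to 1599 probe sets, and those days from each other by 116 to 186. A divergent day 20 alone could raise these shares, so they do not show an order among the days.

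The median log2 fold was 1.82 for meiotic prophase and 0.85 for unfolded protein response genes, above all random lists, and fell by 0.90 for undifferentiated spermatogonia and by 1.37 for GDNF and FGF signalling, below all of them. The medians of cholesterol synthesis (-0.58), oxidative phosphorylation (-0.37), matrix (0.20) and interferon response genes (-0.44) stayed inside the tails, although the mean over a gene's probe sets gave 0.64 for matrix and -0.38 for cholesterol synthesis genes and a floor of 100 gave -1.19 for interferon response genes. Other lists inside the tails moved more, namely general germ cell genes from -0.11 to 1.75 with type A alone, which leaves 3 genes, and with a floor of 100 steroidogenic genes from 0.10 to 1.23 and haploid spermatid genes from 0.04 to 0.79. No random lists were drawn for these settings. In limma's test of a straight line on log2 culture day, 0 of 16066 probe sets passed in either direction, with a smallest adjusted p of 0.355, and 592 rising and 908 falling ones had an unadjusted p under 0.05. Of the 12 orderings of the days, 3 including the real one gave at least as many as its 1500. On culture day itself, 588 rose and 837 fell, and the log2 slope gave 874 and 940 without day 1, 5 and 10 without day 10, and 5 and 19 without day 20.

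On day 20, cells on MSC1 feeders carried more transcripts of undifferentiated spermatogonia and fewer of meiotic prophase than cells on STO feeders. This comparison and that of STO day 20 with day 1 share the STO day 20 library, so they are not independent. A trait of that 1 library would enter both. Ret was at least 22.9-fold higher on MSC1 (signal 1145 against 48.6), Gfra1 6.41-fold, Nanos3 at least 6.998-fold and the transcriptional repressor gene Bcl6b 5.90-fold. In the list of undifferentiated spermatogonia 5 of 23 genes were higher and 1 was lower, Epcam at 3.15-fold. In the GDNF and FGF signalling list 5 of 17 were higher, with Etv4 at 6.03-fold and Spry4 at 3.17-fold. Meiotic prophase genes were lower for 3 of 8, with Spo11 at 20.5-fold, Sycp2 at 7.21-fold and Smc1b at 4.27-fold.

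Interferon response genes were higher on MSC1 for 5 of 18, led by Psmb8 at 16.2-fold and Psmb9 at least 8.77-fold. Oxidative phosphorylation genes were higher for 3 of 21, the cytochrome oxidase genes Cox8a (4.59-fold), Cox5b (3.64-fold) and Cox4i1 (3.14-fold), and lower for Ndufv2 of complex I at 9.90-fold. Of 18 unfolded protein response genes 5 were lower, among them Canx at 4.85-fold and Hsp90b1 at 4.005-fold, and Chac1 was 3.73-fold higher. Cholesterol synthesis genes were lower for 2 of 15, Sqle at least 8.86-fold and Cyp51 at 4.72-fold. A Sertoli cell gene, Cldn11, was 11.1-fold higher on MSC1, the feeder made of Sertoli cells, with a signal of 616 against 55.6, and the other 18 measured Sertoli genes passed no call. Of 12 myoid genes 1 was higher, the tropomyosin gene Tpm2 at 3.25-fold, and of 27 matrix genes 1 was higher, Sparc at 3.63-fold. Star was 3.54-fold lower and Hsd11b1 at least 5.16-fold lower, out of 9 steroidogenic genes.

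The largest folds on MSC1 among genes above the floor on both sides were those of Ssh1 at 62.3-fold, C20h6orf15 at 35.8-fold, the basement membrane gene Nid2 at 27.4-fold, Fbxo41 at 20.7-fold and the epithelial splicing factor gene Esrp1 at 18.0-fold. Lower were Itsn2, a scaffold of endocytosis, at 21.7-fold, Spo11, Bod1l1 at 13.7-fold and Spdya, an activator of the kinase CDK2, at 11.97-fold. Itsn2 (gene 313934) lies on chromosome 6 from 33336086 to 33446818 (GRCr8). There were 878 probe sets higher and 727 lower, a share higher of 54.7%, and with arrays scaled to the same 75th percentile these were 655 and 990, a share of 39.8%. The median log2 fold of all genes was 0.23, and 0.04 after quantile normalization. Relative to 0.23 the list medians were 1.00 for undifferentiated spermatogonia, 1.00 for GDNF and FGF signalling, 0.99 for interferon response, 0.78 for myoid genes, 0.51 for oxidative phosphorylation, -1.50 for meiotic prophase and -0.80 for the unfolded protein response, all in a tail of the random lists. The lists of undifferentiated spermatogonia and of GDNF and FGF signalling share 8 genes, so their medians are not separate results. Against STO day 10 in place of day 20, a setting chosen after the data were seen, 338 were higher on MSC1 and 219 lower, of which 221 and 91 were called against day 20 as well. The ratio of the 3' to the 5' signal on type A was 27.4 on MSC1 and 14.7 on STO day 20 for Gapdh but 25.8 and 37.0 for actin, so the genes ranked the libraries in opposite order.

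**Figure D3:**
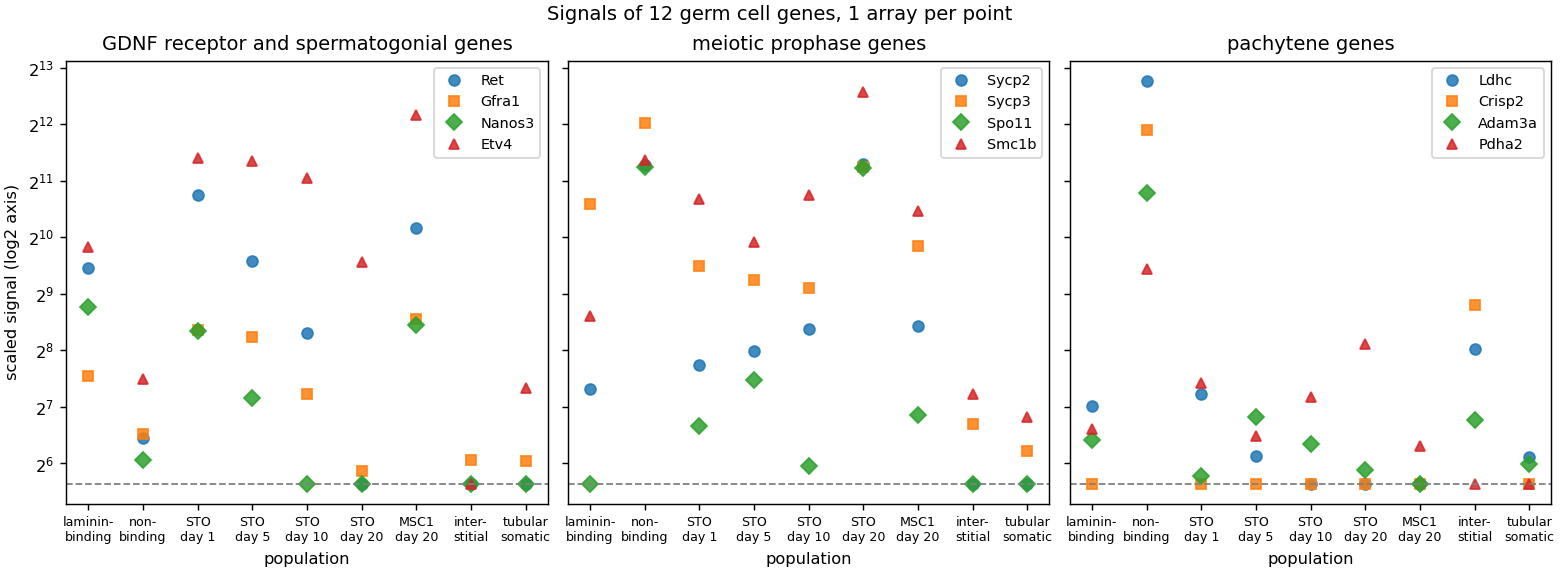
Scaled signal on a log2 axis (vertical) of 12 genes in the 9 populations (horizontal), 1 point per gene and population, in panels of spermatogonial, meiotic prophase and pachytene genes, with values under the floor of 50 (dashed line) drawn at it. Ret stands at 48.6 on STO day 20 and 1145 on MSC1 day 20 before the floor, and Spo11 at 2381 on STO day 20 and 2417 in non-binding cells, while Ldhc at 6938.0 stands out in non-binding cells.

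The difference between the feeders on day 20 ran along the difference between the laminin fractions. Probe sets higher in binding than in non-binding cells were also higher on MSC1 than on STO for 316 of 1132, where 32.0 would be shared by independent lists. Those lower in binding cells were lower on MSC1 for 295 of 1186, where 27.8 would be shared. Opposite calls were made for 8 and 12 probe sets, where independent lists would share 26.5 and 33.5. The numbers for independent lists were taken over all 31042 counted probe sets, including dim ones that could not be called. Among bright probe sets alone they would be larger. Across 17080 probe sets, which are not independent replicates, the log2 folds of binding over non-binding cells and of STO over MSC1, which use no common array, had a Pearson r of -0.49 and a Spearman rank correlation of -0.48. After quantile normalization r was -0.47. Both contrasts set a more strongly scaled library against a less scaled one. On types A and B the scale factors were 1.03 and 4.01 in binding and 0.582 and 2.12 in non-binding cells. They were 1.10 and 3.10 on MSC1 and 0.670 and 1.44 on STO day 20. A shared effect of array brightness on the overlap and on r was not tested. The folds of MSC1 over STO day 20 and of STO day 10 over day 1 had an r of -0.29 and a rank correlation of -0.24. These were the 2 relations examined, and neither has a p-value.

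The tubular somatic fraction was higher in Sertoli cell and interferon response transcripts, and the interstitial fraction in those of Leydig cells, matrix and macrophages. Of 17 measured Sertoli genes 6 were higher in the tubular fraction, including Clu, a secreted chaperone, at 10.4-fold, the inhibin subunit gene Inha at 8.37-fold and the androgen carrier gene Shbg at 7.83-fold. Steroidogenic genes, whose products make testosterone in Leydig cells, were lower for 4 of 12, with Hsd3b1 at least 48.0-fold and Cyp11a1 at least 13.1-fold. Of 29 matrix genes 15 were lower and 3 higher, with the growth factor receptor gene Pdgfra at least 72.4-fold lower, Lum at 24.8-fold and Col3a1 at 13.9-fold, and Ccn1 at least 17.9-fold higher. Macrophage and leukocyte genes were lower for 9 of 23, led by Cd68 at 18.7-fold and the mannose receptor gene Mrc1 at 13.7-fold. Interferon response genes were higher for 8 of 20, with Mx2 at least 49.5-fold, Isg15 at 40.7-fold (signal 24229.7 against 596) and Oas1a at 21.8-fold.

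The smooth muscle genes Tagln and Myl9 were 14.6-fold and 10.6-fold higher in the tubular fraction, 2 of 13 measured. Cell cycle genes were lower there for 10 of 30, such as the kinesin gene Kif20a at 7.64-fold and the cyclin gene Ccna2 at 5.48-fold. Oxidative stress genes were lower for 4 of 15, including the heme oxygenase gene Hmox1 at 7.78-fold and the cystine transporter gene Slc7a11 at 5.61-fold. Cholesterol synthesis genes were lower for 2 of 16, Sc5d at 3.75-fold and Msmo1 at 3.02-fold. Immediate early genes went both ways, as Atf3 was 5.75-fold higher and Egr1, Egr2, Klf4 and Myc were 4.92-fold, 7.04-fold, 5.46-fold and 3.84-fold lower. None of 8 endothelial genes and none of 5 haploid spermatid genes passed a call by the probe set used for the lists. The endothelial gene Ptprb was at least 7.86-fold higher in the tubular fraction by another probe set, on type B.

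By size of fold, among genes above the floor on both sides, the first were Gbp4, an interferon-induced GTPase, at 47.1-fold higher, Isg15, Ildr2 at 32.7-fold, Mbnl3 at 29.9-fold, and Itga6, a subunit of laminin receptors, at 29.3-fold. Lower were the chemokine gene Cxcl12 at 64.7-fold, Lnx1 at 60.9-fold, Steap4 at 55.6-fold and Cd163, a scavenger receptor of macrophages, at 48.7-fold by a probe set on type B and 3.54-fold by the brighter one on the same type that stands for it in its list. Gbp4 (gene 310917) lies on chromosome 2 from 233978163 to 233992124 and Cxcl12 (gene 24772) on chromosome 4 from 152060781 to 152073628 (GRCr8). In the tubular fraction 789 probe sets were higher and 983 lower. The median log2 fold was 1.15 for interferon response genes, above all random lists, 0.74 for Sertoli genes and 1.03 for haploid spermatid genes, above at least 99.18% of them. It was -1.78 for matrix, -1.50 for steroidogenic, -1.41 for macrophage and leukocyte and -1.35 for cell cycle genes, below all random lists, and -0.74 for oxidative stress and -0.73 for cholesterol synthesis genes, below all but 0.335% of them or fewer. Under the alternatives the Sertoli median went down to 0.38 with quantile normalization, the haploid median, which rests on 5 genes, to 0.29 at a floor of 25, and the steroidogenic median was -0.78 at a floor of 100.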

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

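The settings of single days, single somatic fractions and the laminin comparison without somatic probe sets were chosen only after the results were seen. With a 2-fold threshold, which admits more probe sets by its construction, the higher and lower counts were 2438 and 2141 for laminin-binding over non-binding cells, 2011 and 1533 against both somatic fractions, 1558 and 1680 for STO day 20 over day 1, 1984 and 1779 for MSC1 over STO and 1699 and 1928 for the tubular over the interstitial fraction. Without a minimum on the brighter side, 1363 were higher on MSC1, in place of 878, also by construction. Leaving out probe sets higher in a somatic fraction left 642 higher in binding cells. Against the interstitial fraction alone 1791 were higher and 2122 lower, and 1631 were lower than in the tubular fraction alone, since 1 condition was dropped. With STO day 10 for day 20 the STO series gave 44 higher and 142 lower and the MSC1 comparison 338 and 219; the cause was not tested. The trend, with 0 rising and 0 falling, gave 588 and 837 on culture day, 0 to 874 rising and 0 to 940 falling without 1 of the days, 5 and 10 without day 10 and 5 and 19 without day 20; the cause was not tested. The mean array spread was 0.21 in place of 0.25 for probe sets with a mean signal of at least 250. All other counts of these comparisons stayed within 1.5 times the main count, and a floor of 25 cannot change them by its construction. Of the 245 alternative values of the 41 list medians in a tail, 51 moved by more than the array spread, 32 nearer to 0 and 19 farther from it, and none changed sign. Of 400 values of the 100 named genes, 77 moved by more than this spread, 63 nearer to 0, and 30 by over 1.5 times, 29 of them with a floor of 100, and all stayed past 3-fold. Signals under the floor limit the folds of dim genes to lower bounds.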

Other observations

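All tests of explanations in this part were chosen only after the results were seen, and so were the pairs of populations set side by side in it. Cells on STO feeders for 1 day were lower in immediate early transcripts than laminin-binding cells for 7 of 17 genes, with the transcription factor genes Atf3 at 15.9-fold and Fosb at 15.4-fold, and none was higher. Interferon response genes were lower on STO day 1 for 5 of 18, led by Irf7, a transcription factor of this response, at 10.96-fold, whose signal was highest in the tubular somatic fraction (6321). Sertoli genes were lower too, with a median log2 fold of -0.62, below all but 0.33% of random lists, and Cldn11 at 7.21-fold lower. Col5a2, a fibrillar collagen gene, was 22.8-fold higher on STO day 1 by its brightest probe set, while another read 86.2 against 58.2, and 6 of 27 matrix genes were higher and 2 lower. The immediate early and interferon response lists had a median log2 fold of -1.37 and -0.77, below all random lists, and the matrix list one of 0.23, inside the tails. Cholesterol synthesis (-0.57), oxidative stress (-0.54) and unfolded protein response genes (-0.47) were in the lower tail as well. GDNF and FGF signalling (0.76) and glycolysis and hypoxia genes (0.47) were in the upper tail. Of the 7 immediate early genes higher in laminin-binding than in non-binding cells, 6 were also brighter than in either somatic library and Egr2 was not. The ratio of the 3' to the 5' signal was higher on STO day 1 than in binding cells. For Gapdh it was 20.7 against 7.07 on type A and 19.9 against 8.83 on type B. For actin it was 71.2 against 21.6 on type A and 59.8 against 13.1 on type B. A part of RNA quality in the folds of STO day 1 over binding cells was not tested.

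Cells on STO for 20 days were higher than laminin non-binding cells in meiotic prophase transcripts as a list and lower in pachytene ones. None of 8 meiotic prophase genes differed between them by 3-fold, but their median log2 fold was 0.72, above 99.4% of random lists, while 8 of 16 pachytene genes were lower on STO day 20, with a median of -2.16. Cage1 was 52.0-fold lower on STO day 20, Adam3a, of the sperm surface, 29.5-fold and Lrrc23, of the sperm flagellum, 37.8-fold. Matrix genes were higher on STO day 20 than in non-binding cells for 9 of 25, such as Lox at 11.1-fold and Igfbp7 at 11.1-fold, with a list median of 1.21. The number of probe sets past the threshold was 1164 between STO day 20 and non-binding cells, 2665 between STO day 20 and binding cells, 836 between STO day 1 and binding cells, and 1442 between MSC1 day 20 and binding cells.

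Meiotic prophase genes were higher in the STO day 20 library than on day 1, with Spo11 at 23.5-fold. Carry-over of cells like the non-binding cells would bring their pachytene transcripts, yet the 8 pachytene genes called in the laminin comparison had a median of at most 7.80% of their non-binding signal on STO day 20 (0.721% to 39.7%, with signals under the floor raised to it), where the 4 meiotic genes called in the same way had 131% (98.5% to 231%). Crem of the pachytene list, which is not among these 8, goes the other way by its probe set on type B. It read 1506 on STO day 20 and 2802 in non-binding cells. The choice among the scalings does not account for it, as the lowest median under the other scalings was 1.83. Those scalings moved the median of all genes only from -0.11 to -0.03 and -0.06. A large fall of the list median was therefore not possible, and this was no strong test of between-array scaling. An exchange of the labels of the day 20 cultures cannot be told apart, because the correlation of MSC1 over STO day 20 with STO day 10 over day 1 was -0.29 and Cldn11 of Sertoli cells read 616 in the library labelled MSC1 (637 in laminin-binding cells) and 55.6 to 88.3 in those labelled STO, which speaks against it, while the library labelled MSC1 differed from STO days 1, 5 and 10 by 423, 321 and 557 probe sets and the one labelled STO day 20 by 1440, 1599 and 774, which speaks for it but would also be seen if MSC1 feeders kept cells as they were. A candidate explanation that stays open and untested is that germ cells entered early meiosis between days 10 and 20, or that cells in early prophase made up more of the culture.

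Interferon response genes were higher in the tubular somatic library than in the interstitial library, with Isg15 at 40.7-fold. Macrophages and other leukocytes in the tubular fraction would raise their own transcripts, but the median log2 fold of the macrophage and leukocyte list was -1.41, with Cd68 at a signal 18.7-fold lower. The choice among the scalings does not account for the difference, as the lowest interferon median under the other scalings was 1.10. Those scalings moved the median of all genes only from 0.003 to 0.03 and 0.06, so this was no strong test of between-array scaling. An interferon response of tubular somatic cells, in the animals or during isolation, may account for the difference, and 1 library per fraction leaves this open as a hypothesis.

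In all 5 libraries of cells on feeder layers, 14 probe sets were at least 3-fold higher than in all 4 others, and 4 were lower in the same way. The named ones, chosen after their values were seen, were probe sets on type B of the elongation factor gene Eef2, the desaturase gene Scd2 and Fndc3c1. The Eef2 probe set read from 2003 on STO day 20 to 5258 on MSC1 and from 60.2 to 116 in the others. These are signals of single probe sets, and other probe sets of the genes are not given here. Whether they read the rat transcript was not tested, so they do not give the level of the gene. Under the other scalings the lowest number of such probe sets was 11, so most did not depend on the choice among these scalings. RNA of the mouse feeder cells is a candidate source that cannot be told apart from a response of the germ cells to the feeders, since both would be in the same 5 libraries, and the matrix genes that a fibroblast feeder would bring had a median of 0.23 on STO day 1 over laminin-binding cells, above 88.8% of random lists. On STO day 20 over non-binding cells the median of the matrix list was 1.21, above all random lists, with 9 of 25 genes higher and 0 lower. RNA quality cannot be told apart either, since the lowest Gapdh ratio of the 3' to the 5' signal on feeders was 1.30 times the highest elsewhere on type A but 0.896 times on type B, which holds 13 of the 14 probe sets, and for actin it was 0.383 and 0.429 times, which argues against it.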
